A study of Homo sapiens with 12 samples.

How the data were processed

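The series holds 12 RNA sequencing libraries from HMVEC-L cells, primary human lung microvascular endothelial cells grown as a monolayer, in 4 groups of 3 libraries each. The untreated group had neither vehicle nor TNF. The other groups were pretreated for 1 h with 0.4% DMSO, with 10 µM SB203580 or with 100 µM UM101, and then stimulated with 10 ng/ml TNF for 3 h. The labels give a DMSO percentage for the DMSO group alone, so the vehicle of the compound groups is not known. RNA was enriched for poly(A) and sequenced on an Illumina HiSeq instrument, per the labels. Every library was placed in its group by its own title in the labels, and replicate numbers 1 to 3 came from the same titles.

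The authors deposited 1 table per library, with an Ensembl gene identifier and an RPKM value for each gene. Per the submitters' processing notes, TopHat, DESeq and the genome build GRCh38 were used; the part each tool had in the values is not given in the sources used here, nor are their versions, the annotation or the strand setting. Each table listed 60107 genes, except that of untreated replicate 2, with 60105; the 2 genes missing there were left out. Identifiers were matched to GENCODE release 29, which gave a genomic span to 56529 genes (94.05%) and a unique symbol for use in the text to 40119.

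The unit was examined before any test. Each deposited RPKM value times the gene's whole genomic span, introns included, was close to a whole multiple of 1 step per library. For genes under 1000 reads, 94.6% to 94.9% of values lay within 0.05 of a whole number of reads. The deposited RPKM values were therefore taken as reads divided by the whole span of a gene rather than by its exons, which makes genes with long introns look low but leaves ratios between libraries of 1 gene as they are. The step gave the number of reads behind the values, from 104 M (megareads) in UM101 replicate 3 to 183 M in untreated replicate 2. At these depths 1 read in a 10 kb gene was worth 0.000547 to 0.000958 RPKM, and more in a shorter gene. Reads summed over genes came to 1.16 to 1.22 times those depths. Pairs with one gene inside another were compared where the inner gene held a mean of at least 100 reads. The outer gene held about as many reads as the inner, or more, in 97.74% of 1238 pairs on the same strand. On opposite strands this was so in 97.66% of 2265 pairs. With the outer genes shuffled the shares were 69.79% and 80%. Reads of overlapping genes were thus counted for both, on either strand, and reads in introns were probably counted as well. A change therefore need not be that of spliced mRNA alone. Genes whose overlap partner held at least 0.2 times their own reads are named as uncertain in the text. Such a partner was present for 52.7% of the genes tested and for 48.2% to 51.5% of the genes called in each comparison.

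All tests were run on log2(RPKM + 0.5), with no further scaling of the libraries. Genes with at least 0.5 RPKM in at least 3 of the 12 libraries were tested, 13701 in all. Fold changes are differences on that log2(value + 0.5) scale, which understates the change of low genes, also of genes that a long span makes low. limma 3.58.1 in R 4.3.3 fitted 4 group means over all 12 libraries, with 8 residual degrees of freedom, moderated with a mean-variance trend. The contrasts were TNF with DMSO against untreated, SB203580 against DMSO, UM101 against DMSO, and UM101 against SB203580, the last 3 all with TNF. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, and an adjusted p under 0.05 was called a change. Every adjusted p of a gene in the text is from this limma test, unless an alternative is named beside it, whose own fit then gave the value.

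For the 32 gene lists fixed before the data were examined, camera, a test of whether a list moves against the other genes, was run with a preset correlation of 0.01 and adjusted over the lists of a contrast. It was repeated with the correlation estimated from the data, and fry was run as a test of the list on its own. Members of each list were counted by direction, over all genes tested and adjusted over the list alone. Some lists share members, so their results are not independent of each other. The list of mRNAs with AU-rich elements shares genes with those of chemokines, cytokines, immediate-early genes and ERK feedback. Lists of fibroblast and mural cell, epithelial and leukocyte markers were included as signs of other cell types.

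Genes were named by a rule fixed before the data were examined. For each contrast these were the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 1 RPKM in a compared group and no overlap between the libraries of both groups. To these came up to 4 members with the smallest p of each list that passed camera or had at least 3 called members, and a fixed set of p38 pathway and inflammatory genes. A few genes that the rule chose are not reported here. A gene named in one contrast is also given in the others where the compounds are set side by side, and other genes are said to have been chosen after their values were seen. CXCL10 and RPS6KA5, of the fixed set, lay under the filter on low values and were not tested.

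The share of the TNF response left with each compound was the median, over genes called with TNF, of the change from untreated in each library as a percentage of the mean change with DMSO, and groups were compared by a two-sided exact permutation test. Contrasts that share the DMSO libraries were set against 50 simulations in which the compound groups had no effect, with the spread of the real data, and against the overlap of independent lists. The procedure was tested on simulated data for TNF with DMSO against untreated: of 50 genes changed at each fold it called 68% at 1.25-fold, 86% at 1.5-fold, 92% at 2-fold and all at 4-fold with the right sign, and it called 0.0297% of 13471 unchanged genes and 0 of 40 random lists, over 13701 genes fitted. This test and the 50 simulations drew noise for each gene on its own, with the spread fitted by limma. They therefore cannot give the rate of false calls where genes or libraries vary together.

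Alternatives fixed before the data were examined changed 1 choice at a time: the pseudocount, the filter, the threshold, the scaling (median-ratio or quantile), the variance model (no trend, or robust), fits with only the 6 libraries compared, the replicate number as a block, and each replicate left out in turn. CPM (values without the gene span), limma's voom on the reads recovered from the steps, protein-coding genes alone, and genes without an overlap partner were added after the data had been seen. Whole reads were recovered through a span annotation that the authors may not have used, so those reads were not used for the main test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.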

Results

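Gene expression was measured by poly(A)-enriched RNA sequencing in HMVEC-L cells, primary human lung microvascular endothelial cells, the cells that line the small vessels of the lung. The 12 libraries fell into 4 groups of 3, which were untreated cells and cells given TNF (10 ng/ml for 3 h) after 1 h with 0.4% DMSO, 10 µM SB203580 or 100 µM UM101. No vehicle is given for the compound groups, so contrasts with these groups may also hold a difference in vehicle. TNF is an inflammatory cytokine that activates NF-κB and the stress kinase p38. SB203580 is an ATP-competitive inhibitor of p38 catalysis, and the series presents UM101 as a p38α inhibitor that is selective for substrates and leaves catalysis alone. The deposited RPKM values rested on 153, 183 and 131 M reads in untreated replicates 1 to 3, 140, 144 and 122 M with DMSO, 123, 124 and 120 M with SB203580, and 154, 142 and 104 M with UM101. UM101 replicate 3 stood apart: its 10 most abundant genes took 13.2% of reads against 8.51% to 10.9% in the other libraries, and protein-coding genes 80.7% against 82.7% to 84.4%. Changes are log2 fold changes on the log2(RPKM + 0.5) scale with their standard errors (SE), over 3 libraries per group, and adjusted p-values are from limma. Changes written as a fold come from the same scale, so they are smaller than the ratios of the RPKM means printed beside them.

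The first comparison, TNF with DMSO against untreated cells, asked what the cytokine did before any inhibitor. ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615 on GRCh38), a ligand for leukocyte integrins, rose from 5.17 ± 0.246 to 231 ± 3.1 RPKM (mean ± SD, n = 3), a change of 5.35 (SE 0.0435, adjusted p = 5.49e-13). VCAM1 (ENSG00000162692, chromosome 1, 100719742 to 100739045), another integrin ligand, rose from 2.46 ± 0.137 to 60.2 ± 0.696 RPKM, 20.5-fold (adjusted p = 1.97e-12). E-selectin, the rolling receptor encoded by SELE (ENSG00000007908, chromosome 1, 169722641 to 169764705), rose 31.7-fold, and CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), the neutrophil chemokine interleukin-8, rose from 57.4 ± 1.45 to 272 ± 1.7 RPKM. Further large rises were those of TNFAIP2 (5.11), the chemokines CCL5 (5.03), CCL20 (4.76) and CX3CL1 (4.45), and CSF2 (4.59), which encodes GM-CSF, each with an adjusted p of 2.60e-11 or less. The rise of the antisense gene ICAM4-AS1 (5.49) is uncertain because it overlaps ICAM1, and reads of ICAM1, SELE and CCL5 could include those of the overlapping genes LIMASI, C1orf112 and ENSG00000270240.

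Among the largest falls with TNF, SOX18 (ENSG00000203883, chromosome 20, 64047582 to 64049641), a transcription factor of vessel development, fell from 20.3 ± 2.57 to 3.58 ± 0.539 RPKM (-2.35, SE 0.112, adjusted p = 1.05e-07). THBD, which encodes the anticoagulant receptor thrombomodulin, fell 4.21-fold, and ID1, a target of BMP signalling, 4.27-fold. RGS4, a brake on G protein signalling (-2.03), the Wnt antagonist DKK1 (-2.01), the serotonin receptor HTR1B (-2.03), SPAAR (-1.91) and the noncoding LINC02915 (-2.28, overlapped by ENSG00000259345) also fell, with adjusted p of 3.63e-07 or less.

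Of 13701 genes tested, 5292 changed with TNF, 1816 higher and 3476 lower, and 155 of the higher and 73 of the lower changed at least 2-fold. With median-ratio scaling of the libraries the split was 2815 higher and 2783 lower, so that 49.7% of calls were lower against 65.7%. With voom the 2-fold split turned to 409 higher and 538 lower. The libraries of both groups did not overlap for 54.43% of genes, against 10% by chance.

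Inflammatory lists rose as groups with TNF. All 29 measured NF-κB feedback genes and targets rose (29 adjusted over the list alone, camera adjusted p = 4.58e-37), among them the inhibitors NFKBIA (2.84) and TNFAIP3 (3.44) and the adaptor kinase RIPK2 (2.21). Of 15 chemokines 13 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 4.42e-16), with CXCL2 at 3.74, CXCL3 at 3.9 and CCL2, which attracts monocytes, at 2.01. Leukocyte adhesion molecules rose in 10 and fell in 2 of 14 (10 and 2 adjusted over the list alone, camera adjusted p = 1.69e-10), and the syndecan SDC4 was among those that rose (2.0). Cytokines and growth factors rose in 11 and fell in 1 of 16 (12 and 1 adjusted over the list alone, camera adjusted p = 9.36e-12), including LIF (2.83), LTB (3.48) and CSF1 (2.35). mRNAs with AU-rich elements, sequences that shorten mRNA life, rose in 22 and fell in 6 of 31 (22 and 7 adjusted over the list alone, camera adjusted p = 4.42e-16). These 5 calls also held with an estimated correlation.

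Interferon-stimulated genes rose in 23 and fell in 4 of 33 (25 and 4 adjusted over the list alone). The transcription factor IRF1 (2.8), the guanylate-binding proteins GBP1 (1.91) and GBP2 (1.32) and APOL3 (1.65) were among those that rose. Camera gave an adjusted p = 1.15e-16, and adjusted p = 0.074 with an estimated correlation. All 17 genes of MHC class I presentation rose, 17 adjusted over the list alone, with the peptide transporter TAP1 at 1.98, the proteasome subunit PSMB9, whose span overlaps that of TAP1, at 1.88 and HLA-B at 1.04 (camera adjusted p = 4.78e-16; adjusted p = 0.0622 with an estimated correlation). KLF2/4, Notch and flow-response genes fell in 20 and rose in 5 of 26 (20 and 5 adjusted over the list alone). The list mixes genes of several pathways, so its direction does not stand for a state of flow. APLN (-1.78) and NR2F2 (-0.86) fell while the Notch target HEY1 rose (1.06). Camera gave an adjusted p = 0.00383, held in 18 of 19 alternatives, and adjusted p = 0.677 with an estimated correlation. Endothelial identity markers fell in 20 and rose in 4 of 30 (22 and 4 adjusted over the list alone, camera adjusted p = 0.000272; adjusted p = 0.561 with an estimated correlation), with the VEGF receptor KDR, overlapped by ENSG00000250646, at -1.05 and PALMD at -1.45.

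The other 23 lists did not pass camera with TNF (lowest camera adjusted p = 0.0677), though single members changed. The matrix protease gene MMP10, overlapped by WTAPP1, rose by 1.86 and the cholesterol exporter ABCG1 by 0.46. Of 7 measured fibroblast and mural cell markers 1, POSTN, fell (1 adjusted over the list alone, camera adjusted p = 0.983), of 3 epithelial markers 3, KRT19, AGER and CLDN7 (overlapped by ENSG00000262302), fell (3 adjusted over the list alone, camera adjusted p = 0.0771), and of 4 leukocyte markers 1, CSF1R (overlapped by RPL7P1), rose and 1, MRC1, fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.707). By fry, which does not compare a list with other genes, 9 of these 23 lists passed, the epithelial (adjusted p = 4.32e-06) and leukocyte markers (0.0308) among them, both downward. All markers of other cell types were named after their values were seen. Of the p38 pathway genes, MAPK14, which encodes p38α, fell by 0.27 (adjusted p = 4.50e-05) and ZFP36, whose protein destabilises AU-rich mRNAs, rose by 1.54 (adjusted p = 1.80e-07). MAPKAPK3 (-0.18), RPS6KA4 (-0.23) and the phosphatase gene DUSP1 (-0.95, overlapped by ENSG00000253736) also fell, and PTGS2 (0.63) and IL6 (0.83, inside STEAP1B) rose. MAPK11 (-0.01, 95% interval -0.13 to 0.12), MAPKAPK2 (0.08, overlapped by ENSG00000224114), HSPB1 (-0.15), CSF3 (0.03) and CYP1A1 (0.16) did not pass. The untreated cells had no vehicle, so this comparison holds TNF and DMSO together. MAPKAPK2 (0.13) and CYP1A1 (0.193) passed under median-ratio scaling, and both (0.132 and 0.199) and HSPB1 (-0.306) under quantile normalization. CYP1A1 also passed without DMSO replicate 1 (0.193), with a pseudocount of 1 (0.116), with voom (0.238) and among protein-coding genes (0.157).

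**Figure D1:**
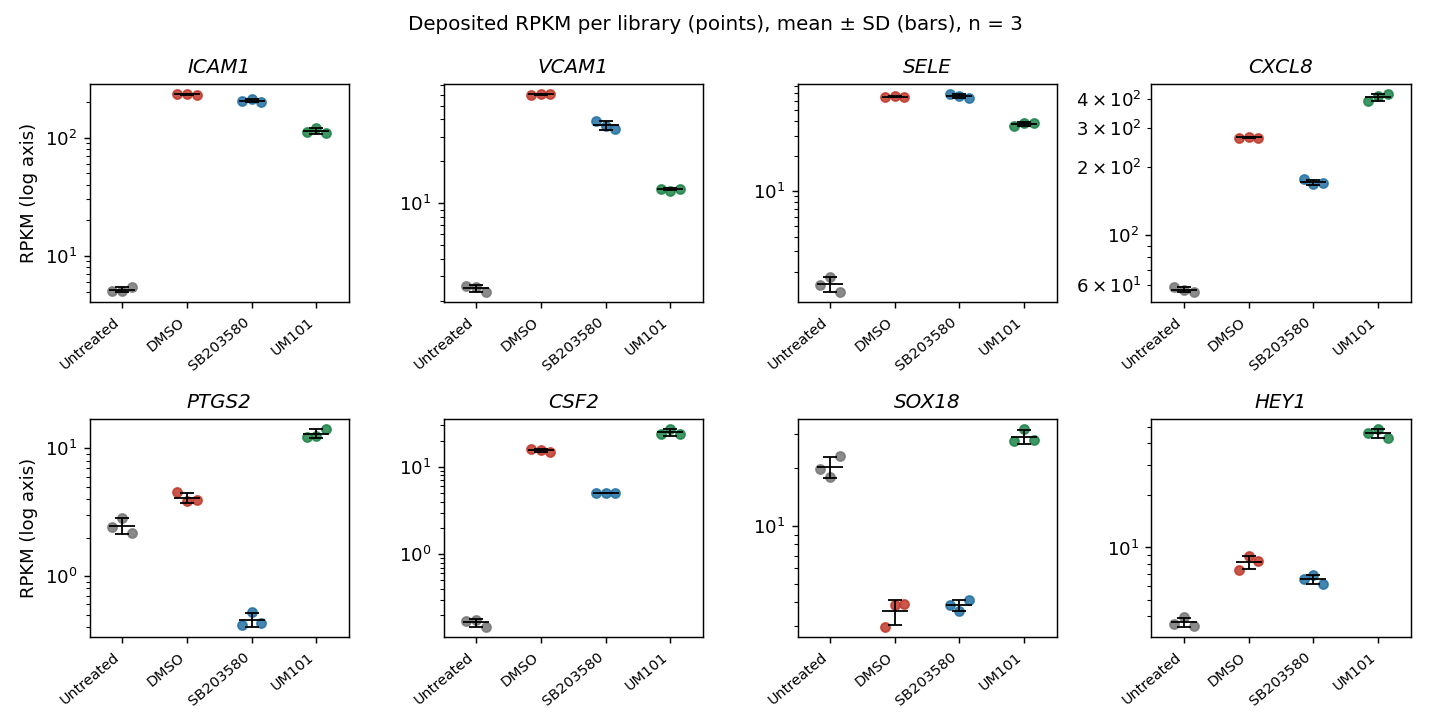
RPKM on log axes for 8 genes in each library (points), with mean ± SD (bars, n = 3), in untreated cells and in cells given TNF after DMSO, SB203580 or UM101. VCAM1 rose to 60.2 RPKM with TNF and stood at 36.3 with SB203580 and 12.6 with UM101, while PTGS2 stood at 4.11, 0.455 and 13.

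The second comparison asked what catalytic p38 inhibition with SB203580 did to the cells under TNF, against DMSO with TNF. PTGS2 (ENSG00000073756, chromosome 1, 186671791 to 186680427), the inducible cyclooxygenase of prostaglandin synthesis, fell from 4.11 ± 0.376 to 0.455 ± 0.0575 RPKM (-2.27, SE 0.093, adjusted p = 9.47e-07). CSF2 (ENSG00000164400, chromosome 5, 132073790 to 132076170) fell from 15.5 ± 0.748 to 5.04 ± 0.0521 RPKM, 2.89-fold, and the vasoconstrictor gene EDN1 (ENSG00000078401, chromosome 6, 12290363 to 12297194) from 34.7 ± 1.03 to 14.9 ± 0.619 RPKM, 2.29-fold (adjusted p = 5.23e-07 and 2.93e-07). The stress cytokine GDF15 (-1.12), TCIM (-1.14), the TNF family gene TNFSF18 (-1.1, overlapped by ENSG00000224228) and UBD (-1.25), a ubiquitin-like modifier whose span overlaps OR2I1P, fell as well, with adjusted p of 1.59e-05 or less. The fall of MIR4497 (-1.14) is uncertain, since it lies inside TRPV4 and stood at only 0, 0.632 and 0.281 RPKM with SB203580. The homeobox gene HLX (1.16), the small GTPase RASD1 (1.14), the immediate-early factor EGR1 (1.12) and the Notch ligand DLL4 (0.9) rose, with adjusted p of 0.000161 or less. The rises of SNORD116-28 (1.35), SYNM-AS2 (0.94) and NR4A1AS (0.94) are uncertain, as they overlap SNHG14, SYNM and NR4A1. SNORD116-28 also stood at only 0.236, 0.306 and 0 RPKM with DMSO.

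SB203580 changed 3161 of 13701 genes, 1690 higher and 1471 lower, and 7 of the higher and 13 of the lower changed at least 2-fold. The larger side turned with scaling, to 1843 higher and 1971 lower with median-ratio scaling and 1807 and 2036 with quantile normalization. The 2-fold split was 30 higher and 33 lower with a pseudocount of 0.1, and turned to 156 and 82 with voom and to 12 and 11 without DMSO replicate 2. The groups' libraries did not overlap for 37.89% of genes, against 10% by chance.

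Cytokines and growth factors were the list that moved furthest with SB203580. They fell in 14 of 16 and rose in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 5.09e-14), with IL1B at -0.98, INHBA at -0.72, IL6 at -0.61 and CSF3 at -0.86. This call alone also held with an estimated correlation. NF-κB feedback genes and targets fell in 18 and rose in 2 of 29 (18 and 2 adjusted over the list alone, camera adjusted p = 1.78e-07; adjusted p = 0.55 with an estimated correlation), with TNFAIP2 at -0.69 and the deubiquitinase gene CYLD, overlapped by ENSG00000260616, at -0.61. AU-rich mRNAs fell in 20 and rose in 5 of 31 (20 and 5 adjusted over the list alone, camera adjusted p = 2.08e-07; adjusted p = 0.55 with an estimated correlation). Chemokines fell in 8 and rose in 4 of 15 (8 and 4 adjusted over the list alone), with CXCL5 at -0.96, CXCL8 at -0.66, CXCL3 at -0.52 and CCL2 at -0.56. Camera gave an adjusted p = 0.0286 for chemokines, held in 16 of 19 alternatives, and adjusted p = 0.588 with an estimated correlation.

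Interferon-stimulated genes fell in 18 and rose in 2 of 33 with SB203580 (19 and 2 adjusted over the list alone, camera adjusted p = 2.7e-06; adjusted p = 0.588 with an estimated correlation), with GBP1 at -0.76 and APOL3 at -0.68, whereas the RIG-I regulator TRIM25 rose by 0.56. MHC class I genes fell in 10 of 17 (12 fell and 1 rose adjusted over the list alone, camera adjusted p = 6.3e-06, held in 18 of 19 alternatives; adjusted p = 0.588 with an estimated correlation), for example HLA-F (-0.55, overlapped by ENSG00000225864) and HLA-B (-0.41). Junction and barrier genes fell in 13 and rose in 3 of 32 (14 and 3 adjusted over the list alone, camera adjusted p = 0.00403; adjusted p = 0.746 with an estimated correlation). Among those that rose was the Tie2 ligand ANGPT2, overlapped by MCPH1, by 0.67. ERK feedback genes and MAP kinase phosphatases were the list that rose, 8 up and 3 down of 18 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00913; adjusted p = 0.746 with an estimated correlation), with the ERK inhibitor SPRY4 at 0.63, the phosphatase gene DUSP7 at 0.58 and cyclin D1 (CCND1, overlapped by LTO1) at 0.46. Immediate-early and CREB targets fell in 11 and rose in 4 of 26 (11 and 5 adjusted over the list alone, camera adjusted p = 0.024, held in 13 of 19 alternatives; adjusted p = 0.76 with an estimated correlation), KLF10 at -0.71 and ATF3 at -0.41 among them. Heat shock genes fell in 7 and rose in 1 of 21 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00819; adjusted p = 0.746 with an estimated correlation), such as DNAJA1 (-0.45) and DNAJB4 (-0.62, overlapped by GIPC2).

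Leukocyte adhesion molecules did not pass camera with SB203580 but passed fry downward (adjusted p = 0.0212, median 0.0114 and mean -0.0975), with 5 lower and 4 higher of 14 (camera adjusted p = 0.662; 5 and 4 adjusted over the list alone). VCAM1 fell 1.65-fold and ICAM1 1.13-fold, while SELE did not pass (0.03, 95% interval -0.12 to 0.19). In the p38 pathway MAPK14 rose by 0.46 (adjusted p = 5.63e-06) and its upstream kinase MAP2K3 by 0.61. DUSP1 (-0.18) and ZFP36 (-0.25) fell, as did CYP1A1 (-0.94), the aryl hydrocarbon receptor target. MAPK11 (0.01), MAPKAPK2 (0.0), MAPKAPK3 (0.0), RPS6KA4 (0.16) and HSPB1 (0.22) did not pass. RPS6KA4 (0.154) passed under median-ratio scaling, and RPS6KA4 (0.167) and HSPB1 (0.295) under quantile normalization. Both also passed without SB203580 replicate 1 (0.207 and 0.306), as CPM (0.174 and 0.223), with voom (0.175 and 0.224) and among protein-coding genes (0.163 and 0.223). DUSP1 lost its call without DMSO replicate 2 or 3 or SB203580 replicate 1 or 2 (-0.173 to -0.184, adjusted p = 0.0559 to 0.068). ZFP36 lost its call with no filter (adjusted p = 0.0922), with the replicate number as a block (0.0633) or without any of these libraries or SB203580 replicate 3 (-0.214 to -0.277, adjusted p = 0.0603 to 0.132). ICAM1 lost its call under quantile normalization (-0.135, adjusted p = 0.0534) or without DMSO replicate 2 (-0.172, 0.0505) or SB203580 replicate 3 (-0.158, 0.0587). SNORD116-28 lost its call without DMSO replicate 3 (1.14, adjusted p = 0.0512). MIR4497 lost its call with no filter (adjusted p = 0.0759) or without DMSO replicate 2 (-0.959, 0.101) or 3 (-1.09, 0.0824) or SB203580 replicate 1 (-0.833, 0.0894) or 3 (-1.15, 0.0685). A pseudocount of 0.1 moved low genes to 2.43 for SNORD116-28, -2.05 for MIR4497, 1.51 for NR4A1AS, -1.55 for CYP1A1 and -0.634 for ATF3.

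The third comparison asked the same of UM101 against DMSO, both with TNF. VCAM1 fell from 60.2 ± 0.696 to 12.6 ± 0.225 RPKM (-2.21, SE 0.0503, adjusted p = 4.56e-09), ICAM1 from 231 ± 3.1 to 113 ± 5.98 and SELE from 64.8 ± 0.636 to 37.8 ± 1.36. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), which restrains glucose uptake and thioredoxin, fell from 29 ± 0.815 to 4.41 ± 0.185 RPKM, 6.0-fold. SOX18 rose from 3.58 ± 0.539 to 29.2 ± 2.49 RPKM (2.87, SE 0.112, adjusted p = 6.80e-08) and ID1 5.57-fold, both lowered by TNF, and the Notch targets HEY1 (ENSG00000164683, chromosome 8, 79764010 to 79767863), HES1 and NRARP rose 5.32-, 3.91- and 3.69-fold. The heat shock gene HSPA6 rose by 2.19 (overlapped by ENSG00000273112), and the rises of THBS1-IT1 (2.61) and NR4A1AS (2.0) are uncertain because they overlap THBS1 and NR4A1. UBD (-2.52), CCL5 (-1.76) and APOL2 (-1.63) fell, as did OR2I1P (-3.72), which overlaps UBD, and the mitochondrial tRNA genes MT-TT (-2.25) and MT-TQ (-1.68, overlapped by MT-TI), all with adjusted p of 0.000414 or less.

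UM101 changed 6306 of 13701 genes, 1548 higher and 4758 lower, and 96 of the higher and 82 of the lower changed at least 2-fold. With median-ratio scaling 3056 were higher and 3378 lower, so that 52.5% of calls were lower against 75.5%, and without UM101 replicate 3 the share was 69.3%. The 2-fold split turned to 173 higher and 191 lower with a pseudocount of 0.1, and to 305 and 431 with voom. The groups' libraries did not overlap for 54.09% of genes, against 10% by chance.

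KLF2/4, Notch and flow-response genes rose furthest as a list with UM101, 22 up and 1 down of 26 (22 and 1 adjusted over the list alone, camera adjusted p = 1.14e-18; adjusted p = 0.181 with an estimated correlation). EDN1 rose from 34.7 ± 1.03 to 77 ± 0.921 RPKM, and the inhibitory SMADs SMAD7 (0.99) and SMAD6 (1.13) rose. TGF-β and SMAD targets rose in 16 and fell in 1 of 24 (16 and 2 adjusted over the list alone, camera adjusted p = 8.85e-12; adjusted p = 0.181 with an estimated correlation), including CCN2 (1.18) and ID2 (1.72). Immediate-early and CREB targets rose in 18 and fell in 5 of 26 (19 and 5 adjusted over the list alone, camera adjusted p = 1.34e-11; adjusted p = 0.181 with an estimated correlation), with CCN1 from 263 ± 2.21 to 829 ± 36.6 RPKM, FOS at 1.79 and SIK1, which has the near-identical copy SIK1B, at 1.69. AU-rich mRNAs rose in 22 and fell in 5 of 31 (22 and 6 adjusted over the list alone, camera adjusted p = 3.58e-10; adjusted p = 0.184 with an estimated correlation), with CXCL3 at 1.13, CXCL1 at 0.76 and CXCL8 at 0.59. ERK feedback genes rose in 12 and fell in 3 of 18 (12 and 3 adjusted over the list alone, camera adjusted p = 3.7e-05; adjusted p = 0.468 with an estimated correlation), DUSP5 by 0.56 and HBEGF by 0.61, whereas DUSP6, overlapped by ENSG00000274021, fell by 0.83.

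Interferon-stimulated genes fell in 28 and rose in 2 of 33 with UM101 (29 and 2 adjusted over the list alone, camera adjusted p = 2.35e-08; adjusted p = 0.457 with an estimated correlation), among them TRIM21 (-1.19), PARP14 (-1.16) and DTX3L (-1.28, overlapped by PARP9). MHC class I genes fell in 15 of 17 (16 adjusted over the list alone, camera adjusted p = 3.74e-05; adjusted p = 0.487 with an estimated correlation), with TAP1 at -0.91 and TAP2, overlapped by ENSG00000250264, at -0.52. NF-κB feedback genes and targets fell in 23 and rose in 6 of 29 (23 and 6 adjusted over the list alone, camera adjusted p = 0.00119; adjusted p = 0.526 with an estimated correlation), with the superoxide dismutase SOD2 at -1.08, the kinase gene IKBKE, overlapped by IKBKE-AS1, at -0.8 and CD40 at -1.21. Leukocyte adhesion molecules fell in 9 and rose in 2 of 14 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0314, held in 18 of 19 alternatives; adjusted p = 0.505 with an estimated correlation), with CX3CL1 at -1.3. Chemokines did not pass as a list against other genes (camera adjusted p = 0.923), with 7 lower and 4 higher of 15 (8 and 4 adjusted over the list alone), such as CXCL5 at -1.51. Cytokines did not pass either (camera adjusted p = 0.261), though 10 fell and 3 rose of 16 (10 and 4 adjusted over the list alone), with IL1B at -0.92, TNFSF18 at -1.13 and LTB at -1.02. By fry, which tests a list on its own, both lists fell (adjusted p = 0.00235 for chemokines and 1.14e-05 for cytokines).

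Mitochondrial-encoded mRNAs fell in 10 of 13 with UM101 (11 adjusted over the list alone, camera adjusted p = 0.023; adjusted p = 0.712 with an estimated correlation), for example the respiratory complex genes MT-ND6 (-0.64), MT-ND3 (-0.63) and MT-CO3 (-0.58, whose span meets that of MT-ATP6). Their share of reads was 0.994%, 1.06% and 0.95% in UM101 replicates 1 to 3, the lowest in replicate 3, against 1.11% to 1.32% with DMSO. Hypoxia and glycolysis genes rose in 11 and fell in 2 of 25 (11 and 2 adjusted over the list alone, camera adjusted p = 3.74e-05; adjusted p = 0.487 with an estimated correlation), with the repressor BHLHE40 at 1.7 and PFKFB3, a driver of glycolysis, at 0.62. Lists of the cytoskeleton (10 up and 7 down of 28, 10 and 7 adjusted over the list alone, adjusted p = 0.0248, and adjusted p = 0.712 with an estimated correlation) and of coagulation and fibrinolysis passed camera upward (5 up and 2 down of 18, 5 and 2 adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.526 with an estimated correlation). THBS1 rose by 1.01 and THBD by 1.12, and these list calls held in 18 and 14 of 19 alternatives. Lymphatic markers rose in 3 and fell in 1 of 8 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0489; adjusted p = 0.526 with an estimated correlation), with FOXC2, overlapped by FOXC2-AS1, at 1.17, PROX1 at 0.25 and PDPN at -0.27. Endothelial identity markers rose in 9 and fell in 6 of 30 (9 and 6 adjusted over the list alone, camera adjusted p = 0.0489; adjusted p = 0.712 with an estimated correlation). Medians were small for hypoxia and glycolysis (0.06), the cytoskeleton (0.07), coagulation (0.0208) and lymphatic markers (0.0181). The cytoskeleton and identity lists did not pass fry (adjusted p = 0.453 and 0.148). The median of the identity list was -0.0132 against a mean of 0.12 and an upward test, the median was positive under both other scalings, and the identity and lymphatic calls held in 12 and 14 of 19 alternatives.

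Among the p38 pathway genes with UM101, MAPK14 fell by 0.15 (adjusted p = 0.0019), DUSP1 rose by 0.56, ZFP36 by 0.62, ZFP36L1 by 0.79 and HSPB1 by 0.25 (adjusted p = 0.0471). MAPK11 (-0.11), MAPKAPK2 (-0.03), MAPKAPK3 (0.05) and RPS6KA4 (-0.04) did not pass, nor did CCL2 (-0.13) and CYP1A1 (0.06). IL6 rose by 0.14 (adjusted p = 0.0378) and CSF3 fell by 0.49 (adjusted p = 0.0046). HSPB1 lost its call with no filter (adjusted p = 0.111) or without DMSO replicate 1 (0.185, adjusted p = 0.164) or 3 (0.281, 0.0663) or UM101 replicate 1 (0.242, 0.109) or 2 (0.198, 0.151). IL6 lost its call with a pseudocount of 0.1 (adjusted p = 0.0583), no filter (0.0782), as CPM (0.063) or without DMSO replicate 1, 2 or 3 (0.128 to 0.155, adjusted p = 0.0595 to 0.106) or UM101 replicate 1 (0.149, 0.0684) or 3 (0.102, 0.128). CCL2 passed as CPM, with voom and among protein-coding genes (-0.127 in each). MAPKAPK3 passed under median-ratio scaling (0.0955) and quantile normalization (0.107). With a pseudocount of 0.1 SMAD7 stood at 2.11 and SMAD6 at 1.93, while a pseudocount of 1 put SMAD7 at 0.612. Of the marker lists of other cell types, 0 of 7 fibroblast and mural cell markers changed, 1 of 3 epithelial markers, KRT19, rose and 1, AGER, fell, and 2 of 4 leukocyte markers, CSF1R and CORO1A, fell (camera adjusted p = 0.442, 0.923 and 0.923). With SB203580 0 fibroblast and 0 epithelial markers changed and 1 leukocyte marker, MRC1, rose (camera adjusted p = 0.662, 0.662 and 0.387). Adjusted over the list alone, these counts were the same. By fry the epithelial markers passed downward with UM101 (adjusted p = 0.0135). Their median of -0.00166 turned to 0.0664 under median-ratio scaling and 0.0807 under quantile normalization.

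**Figure D2:**
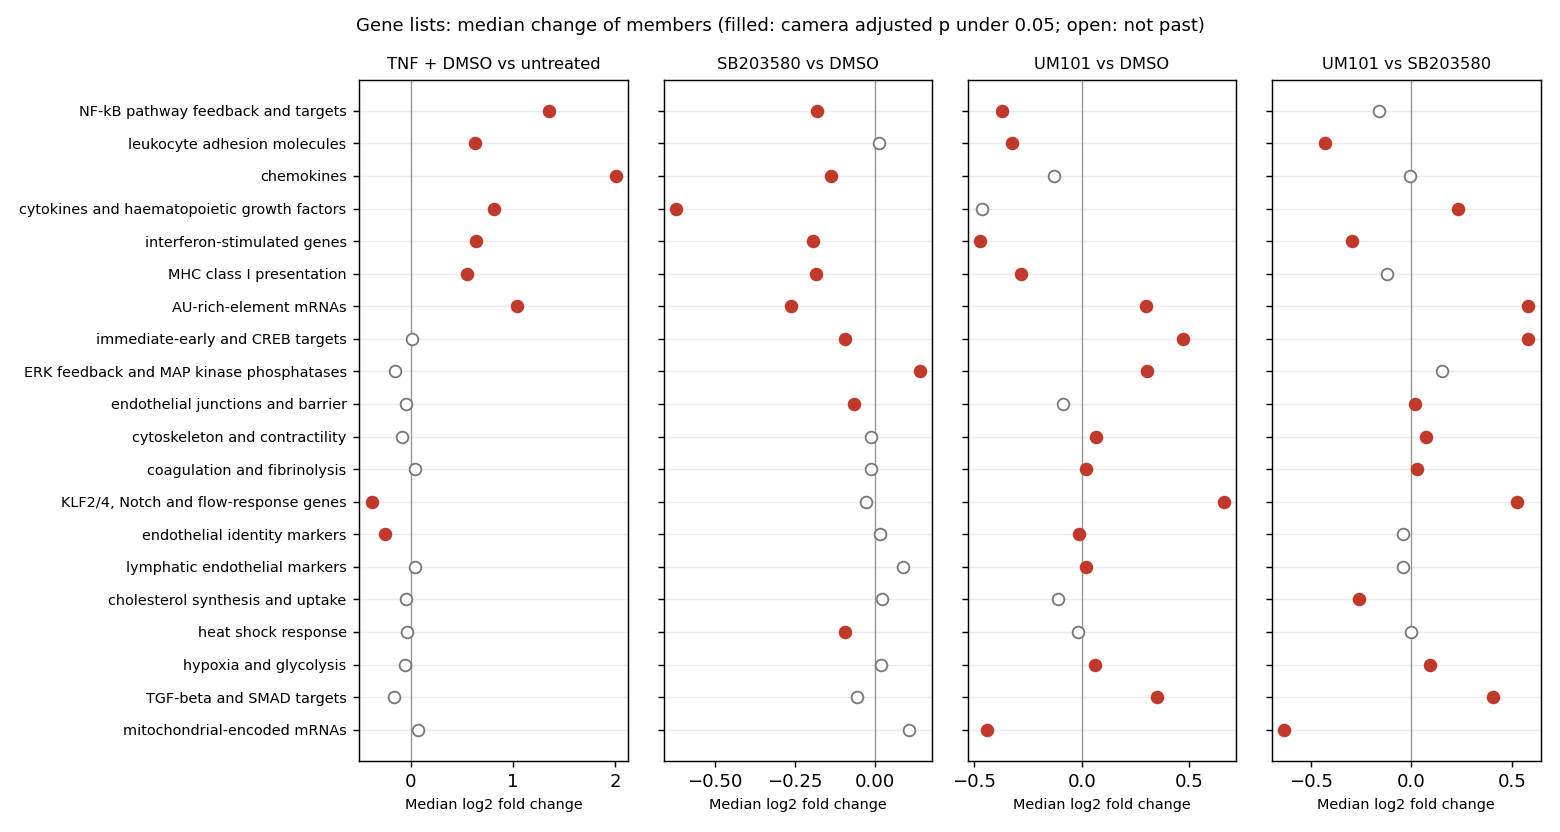
Median log2 fold change of the members of each gene list that passed camera in at least 1 of the 4 comparisons, with filled points for an adjusted p under 0.05 and open points otherwise. The KLF2/4, Notch and flow-response list stood at -0.39 with TNF and 0.66 with UM101, and endothelial identity with UM101 stood at -0.0132, or 0.0574 under median-ratio scaling and 0.0307 under quantile normalization.

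The fourth comparison set UM101 against SB203580 directly, at the doses used, 100 µM and 10 µM, which differ. PTGS2 stood at 13 ± 1.04 RPKM with UM101 and 0.455 ± 0.0575 with SB203580, a difference of 3.82 (SE 0.093, adjusted p = 4.05e-09). HEY1 (6.6-fold), HES1 (6.68-fold), GDF15 (6.46-fold), SOX18 (6.82-fold), ID1 (5.89-fold) and EDN1 (5.05-fold) were higher with UM101. CSF2 stood at 24.9 ± 2.14 against 5.04 ± 0.0521 RPKM and CXCL8 at 409 ± 14.8 against 172 ± 4.26 (2.2 and 1.25). TXNIP (-2.46), VCAM1 (-1.49), CCL5 (-1.99), ICAM1 (-0.85) and SELE (-0.8) were lower with UM101, all with adjusted p of 7.37e-06 or less. Large differences of THBS1-IT1 (3.06), OR2I1P (-2.68), MIR126 (-2.41), DEPP1 (-2.29), RASSF4 (-1.93) and ICAM4 (-1.96) are uncertain, since these overlap THBS1, UBD, EGFL7, each other for DEPP1 and RASSF4, and ICAM4-AS1. MT-TT stood at -2.09.

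In all, 6808 of 13701 genes differed between the compounds, 1759 higher and 5049 lower with UM101, and 125 of the higher and 111 of the lower differed at least 2-fold. With median-ratio scaling 3320 were higher and 3540 lower, 51.6% of calls against 74.2%. The 2-fold split turned to 207 higher and 271 lower with a pseudocount of 0.1, 228 and 326 as CPM, 323 and 748 with voom, and 120 and 123 without UM101 replicate 1. The libraries of the compounds did not overlap for 55.22% of genes, against 10% by chance.

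AU-rich mRNAs were higher with UM101 than with SB203580 in 23 and lower in 4 of 31 (23 and 4 adjusted over the list alone, camera adjusted p = 1.62e-14; adjusted p = 0.161 with an estimated correlation). KLF2/4, Notch and flow-response genes were higher in 16 and lower in 1 of 26 (17 and 2 adjusted over the list alone, camera adjusted p = 2.47e-13; adjusted p = 0.161 with an estimated correlation), and the Notch ligand JAG1 differed by 0.97. Immediate-early and CREB targets were higher in 18 and lower in 5 of 26 (18 and 5 adjusted over the list alone, camera adjusted p = 4.19e-12; adjusted p = 0.161 with an estimated correlation), CCN1 by 1.66 and SIK1 by 2.0. TGF-β and SMAD targets were higher in 16 and lower in 3 of 24 (16 and 3 adjusted over the list alone, camera adjusted p = 6.98e-11; adjusted p = 0.161 with an estimated correlation), with CCN2 at 1.1 and SMAD7 at 1.03. Cytokines were higher in 8 and lower in 3 of 16 (8 and 3 adjusted over the list alone, camera adjusted p = 0.000626; adjusted p = 0.278 with an estimated correlation), with INHBA at 0.89, IL6 at 0.76 and CSF3 at 0.37.

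Hypoxia and glycolysis genes were higher with UM101 in 12 and lower in 6 of 25 (12 and 6 adjusted over the list alone, camera adjusted p = 0.00117; adjusted p = 0.626 with an estimated correlation), with BHLHE40 at 1.64 and VEGFA at 0.56. Coagulation and fibrinolysis genes were higher in 8 and lower in 5 of 18 (8 and 5 adjusted over the list alone, camera adjusted p = 0.035; adjusted p = 0.626 with an estimated correlation), with thrombospondin 1 (THBS1) at 1.84 and the plasminogen activator PLAT at -0.4. Junction and barrier genes were higher in 11 and lower in 7 of 32 (11 and 7 adjusted over the list alone, camera adjusted p = 0.035; adjusted p = 0.704 with an estimated correlation), with ANGPT2 at -1.14. Cytoskeleton genes were higher in 10 and lower in 6 of 28 (11 and 6 adjusted over the list alone, camera adjusted p = 0.0144; adjusted p = 0.704 with an estimated correlation), with CNN3 at -0.22. Medians were small for hypoxia (0.09), coagulation (0.0268), junctions (0.017) and the cytoskeleton (0.07), and the junction and cytoskeleton lists did not pass fry (adjusted p = 0.872 and 0.303). The coagulation and junction calls held in 13 and 17 of 19 alternatives.

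Interferon-stimulated genes were lower with UM101 than with SB203580 in 25 and higher in 2 of 33 (25 and 2 adjusted over the list alone, camera adjusted p = 0.000453; adjusted p = 0.626 with an estimated correlation), with TRIM25 at -1.25 and TRIM21 at -0.73. Leukocyte adhesion molecules were lower in 11 and higher in 3 of 14 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0495, held in 11 of 19 alternatives; adjusted p = 0.626 with an estimated correlation). Mitochondrial mRNAs were lower in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 0.00661; adjusted p = 0.704 with an estimated correlation). Chemokines split, with 6 higher and 7 lower of 15 (6 and 7 adjusted over the list alone, camera adjusted p = 0.296; fry adjusted p = 0.000541, upward, though the median was -0.00517 and the mean -0.074), CXCL3 at 1.64 and CCL2 at 0.43 among the higher. MAPK14 was lower with UM101 (-0.61, adjusted p = 1.46e-07), as were MAP2K3 (-0.82) and RPS6KA4 (-0.21), and DUSP1 (0.75), ZFP36 (0.87), ZFP36L1 (1.24) and CYP1A1 (1.0) were higher. The compounds did not differ past the threshold at MAPK11 (-0.12, 95% interval -0.25 to -0.00), MAPKAPK2 (-0.03, -0.10 to 0.04), MAPKAPK3 (0.04, -0.05 to 0.14) and HSPB1 (0.03, -0.18 to 0.24), intervals that are not adjusted over genes. MAPKAPK3 passed under median-ratio scaling (0.0993) and quantile normalization (0.137), and MAPK11 without UM101 replicate 1 (-0.164), as CPM (-0.132) and among protein-coding genes (-0.125). RPS6KA4 lost its call under median-ratio scaling (adjusted p = 0.0951), as did CSF3 without SB203580 replicate 3 (0.34, adjusted p = 0.0534) or UM101 replicate 2 (0.278, 0.0624). With a pseudocount of 0.1 SMAD7 stood at 2.25 and CYP1A1 at 1.64, and with a pseudocount of 1 SMAD7 at 0.633. Between the compounds 1 of 7 fibroblast and mural cell markers, THY1 (overlapped by USP2-AS1), was lower with UM101 (0 adjusted over the list alone, camera adjusted p = 0.754). Of 3 epithelial markers 1, KRT19, was higher and 1, AGER, lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.725). Of 4 leukocyte markers 2, CSF1R and CORO1A, were lower (2 adjusted over the list alone, camera adjusted p = 0.624, fry adjusted p = 0.00313, downward). The median of the leukocyte markers turned from -0.0825 to 0.00839 under median-ratio scaling and 0.00479 under quantile normalization.

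**Figure D3:**
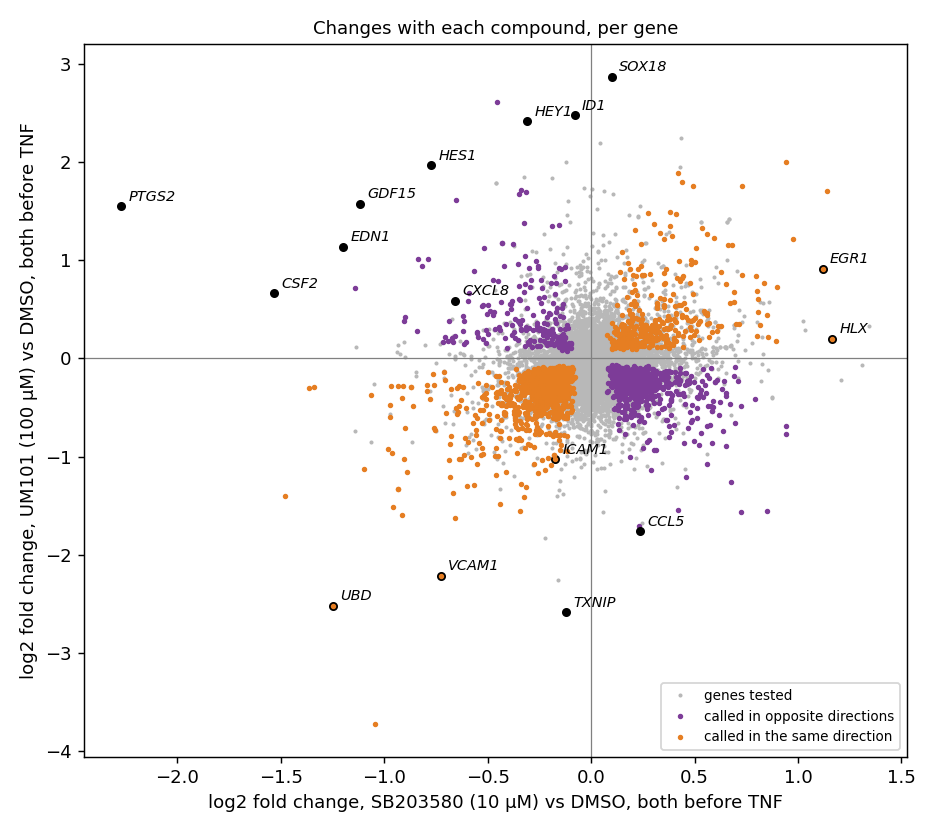
Log2 fold change with SB203580 (10 µM, horizontal axis) and with UM101 (100 µM, vertical axis), each against DMSO and all with TNF, for 13701 genes, with the 853 called in opposite directions and the 1197 called in the same direction in colour. PTGS2 lies at -2.27 and 1.55, CCL5 at 0.24 (a call lost with no filter, adjusted p = 0.0669, with the replicate number as a block, 0.0599, or without DMSO replicate 2 or 3 or SB203580 replicate 2 or 3, 0.181 to 0.231 with adjusted p = 0.0798 to 0.104) and -1.76.

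The compound contrasts were also set against the TNF response. Of the 1816 genes that TNF raised, SB203580 lowered 650 (35.8%) and UM101 1226 (67.5%), against at most 0.0471% in simulated groups with no effect. The simulated groups made almost no calls by construction. They cannot show how much the shared DMSO libraries or a fall of most genes add to these shares. Of the 8409 genes not called with TNF, SB203580 lowered 6.7% and UM101 31.9%. VCAM1 was lowered by both, SELE by UM101, and CSF2 by SB203580, while UM101 raised CSF2 (0.67, adjusted p = 7.34e-06). Among the 155 genes that TNF raised at least 2-fold, SB203580 lowered 105 and raised 16, and UM101 lowered 108 and raised 29, CXCL8, CXCL3 and CSF2 among the last. Of the 3476 genes that TNF lowered, SB203580 raised 867 (24.9%) and UM101 868 (25.0%), SOX18, ID1 and THBD among those raised by UM101. Of genes not called with TNF, SB203580 raised 7.43% and UM101 5.9%. SB203580 lowered 258 (7.42%) of the TNF-lowered genes and UM101 851 (24.5%), the latter under the 31.9% among genes not called with TNF. Median-ratio scaling called another set of genes with TNF, 2815 raised and 2783 lowered. In that set UM101 lowered 49.7% of the raised genes and raised 45.2% of the lowered ones. The median share of the TNF rise left was 73.1% ± 6.34 with SB203580 and 27.8% ± 8.91 with UM101 (mean ± SD, n = 3), against 100% ± 5.13 with DMSO and about 98% in simulated groups with no effect. UM101 replicates 1 to 3 stood at 33.14%, 32.79% and 17.54%, so replicate 3 lowered the UM101 mean. Each compound against DMSO and the compounds against each other gave an exact permutation p = 0.1, the smallest that 3 against 3 libraries can give. Under the other scalings the share was taken over the genes called raised under the same scaling. After median-ratio scaling it was 60.9% with UM101 and 72.2% with SB203580. After quantile normalization it was 57.5% with UM101. Over TNF-lowered genes the share left was 79.6% ± 5.46 with SB203580 and 98.2% ± 15.5 with UM101 (n = 3), with exact permutation p = 0.1 and p = 1 against DMSO. That mean rested on UM101 replicate 3 (116%), since replicates 1 and 2 stood at 90.88% and 87.63%, below every DMSO library (97.9% to 101.1%).

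**Figure D4:**
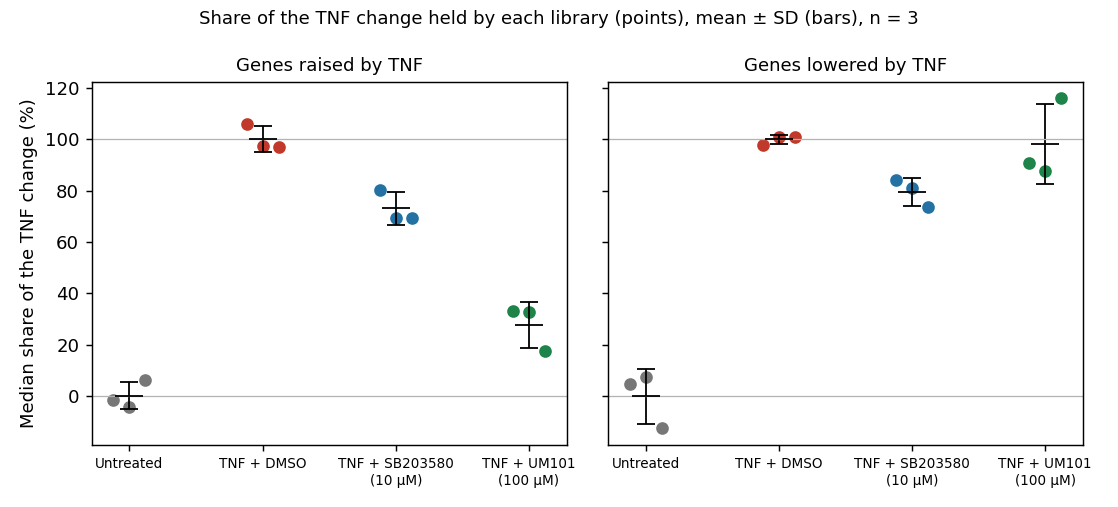
Median share (%) of the TNF change held by each library (points) over genes raised (left) or lowered (right) by TNF, with mean ± SD (bars, n = 3); untreated libraries define 0 and TNF with DMSO 100. Raised genes held 73.1% with SB203580 and 27.8% with UM101. Over the genes called raised under median-ratio scaling these shares were 72.2% and 60.9%.

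Both compounds raised 339 genes and lowered 858, the latter including VCAM1, UBD, CXCL5, IL1B, TNFAIP2 and GBP1, where independent lists would share 190.9 and 510.8. A further 853 genes were called in opposite directions, against 753.1 for independent lists. Of these 638, TRIM25 among them, were higher with SB203580 and lower with UM101 (586.9 for independent lists). The other 215, PTGS2, GDF15, EDN1, HES1 and HEY1 among them, were lower with SB203580 and higher with UM101 (166.2). Scaling moved 2 of these counts past 1.5 times: genes raised by both were 608 under median-ratio scaling and 597 under quantile normalization, and the 215 became 431 and 441. As CPM 821 genes were raised by both, 1358 lowered by both and 1583 opposite (1221 and 362), and with voom 794, 1366 and 1565 (1208 and 357). Without overlap partners they were 219, 472 and 461 (322 and 139). The excess of opposite calls over independent lists was not stable, as it turned to a deficit as CPM (1623 expected), with voom (1597) and among protein-coding genes (804 against 862). The deficit as CPM and with voom lay among genes higher with SB203580 (1295 and 1268 expected), as it did among protein-coding genes (595 against 666). Under median-ratio scaling the 431 fell below the 439.6 of independent lists. Simulated groups with no effect gave at most 1 gene in any class. They made almost no calls, so they cannot show how much overlap the shared DMSO libraries add where genes do change. Fold changes of both compounds correlated at r = 0.198 across genes, which are not independent replicates, against a mean of 0.5 in simulations with no effect, and their covariance was 0.0117 against 0.00627, a difference of 0.00539. The 0.5 follows from sharing the DMSO libraries when only noise is present. It is therefore no baseline for compounds that have effects. The 3 DMSO libraries were too few to split into parts of at least 2, so part of these overlaps may come from the shared DMSO libraries.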

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

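The tests of mitochondrial rRNAs and tRNAs and of the 100 most abundant genes were chosen only after the results were seen, and the other tests before. The compounds moved 853 genes in opposite directions against DMSO, 638 of them higher with SB203580 and lower with UM101, and 215 the reverse. They were selected for opposite calls, so passing the test of the difference adds no support. Named genes higher with UM101 and lower with SB203580 were PTGS2 (difference 3.82), HES1 (2.74), HEY1 (2.72), GDF15 (2.69), EDN1 (2.34), CSF2 (2.2), SIK1 (2.0), THBS1 (1.84) with its overlapping THBS1-IT1 (3.06), CXCL3 (1.64), CXCL8 (1.25) and ZFP36L1 (1.24). Named genes lower with UM101 and higher with SB203580 were TRIM25 (-1.25) and, each with an overlapping gene, CCL5 (-1.99), ANGPT2 (-1.14), MIR126 (-2.41), DEPP1 (-2.29), RASSF4 (-1.93) and ICAM4 (-1.96).

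AU-rich mRNAs were higher with UM101 (median 0.297) and lower with SB203580 (median -0.262). With an estimated correlation the list's calls were lost, with adjusted p = 0.184 for UM101, 0.55 for SB203580 and 0.161 between the compounds. The tables argue against scaling as the cause, since the median difference was 0.684 after median-ratio scaling, and against reads of overlapping genes, since it was 0.581 over members with no overlap partner. Short spans are argued against too, as the list's median lay above 100% of 10000 random lists matched on span and mean value. A candidate biological explanation is that the compounds act differently on the life of these mRNAs, but mRNA decay was not measured and the doses differed.

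More genes were lower than higher with UM101, 75.5% of calls. UM101 replicate 3 alone does not account for this, as 69.3% were lower without it, nor do long spans, with a Spearman correlation of 0.00772 across genes. Scaling and a general fall in expression cannot be told apart, because median-ratio scaling, which gave 52.5%, centres the changes by construction. A larger share of reads in a few genes stays open as well: with reads outside the 100 most abundant genes the median change was -0.0449 against -0.0715, between the bounds set for the test. No measure independent of library totals was used here, so an effect of UM101 on most genes remains untested.

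Mitochondrial mRNAs were lower with UM101 (median -0.44), a call lost with an estimated correlation (adjusted p = 0.712). UM101 replicate 3 alone does not account for this, since the median was -0.371 without it. Fewer mitochondrial transcripts of every kind stay open. The median of the 2 rRNAs was 0.483, but it rested on MT-RNR1 (0.94) against MT-RNR2 (0.02), and poly(A) selection captures rRNA poorly. Mitochondrial tRNAs fell in 18 of 22 (median -0.772), MT-TT (-2.25) and MT-TQ (-1.68, overlapped by MT-TI) among them. That goes with the explanation, but the same limit of poly(A) selection holds for tRNAs. The rise of MT-RNR1 goes against it, and the mRNAs MT-ND4 (0.0832), MT-ND4L (0.0922) and MT-CO1 (-0.146) did not pass. The rRNAs and tRNAs therefore cannot decide the question. Whether UM101 acted on mitochondrial mRNAs in particular was not settled.

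The 6 libraries of a contrast make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5292 genes with TNF, 3161 with SB203580, 6306 with UM101 and 6808 between the compounds, and the highest other split called 0, 0, 1 and 0. In each contrast 1 split, the real one, reached its count.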

How the results depend on the processing

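CPM values, voom, genes without an overlap partner, and the counts of opposite calls under each alternative were chosen only after the data were seen. Of 4262 values of 229 named gene results under the alternatives, 4165 kept direction and side of the threshold, 42 no longer passed, 30 newly passed and 25 changed sign, the last in 9 results that had not passed. The counts of called genes stayed within 1.5 times under both pseudocounts, both scalings, both variance models, fits of 6 libraries and every left-out library, but their higher and lower split moved with scaling.

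Requiring a 2-fold change, a stricter test by construction, left 228 genes with TNF, 20 with SB203580, 178 with UM101 and 236 between the compounds, and an adjusted p under 0.01 left 1757 with SB203580. The 2-fold counts rose to 383, 63, 364 and 478 with a pseudocount of 0.1, which shrinks low genes less, and a pseudocount of 1 gave 143 between the compounds. As CPM they were 585, 101, 372 and 554, with voom 947, 238, 736 and 1071, and without overlap partners 142, 11, 113 and 133, while protein-coding genes alone, also chosen after the data were seen, gave 12 with SB203580, 94 with UM101 and 98 between the compounds. With no filter, which adds genes, 8231 changed with TNF and 10484 differed between the compounds. As CPM, 9393, 5960, 10136 and 11279 genes were called and 2179 shared by both compounds in 1 direction. With voom they were 9564, 5908, 10083, 11123 and 2160, and in both the filter was applied to CPM, so another set of genes was tested. Among genes without an overlap partner, a smaller set, they were 2736, 1729, 3172, 3352 and 691. With an estimated correlation 5, 1, 0 and 0 gene lists passed in place of 9, 10, 15 and 13. By fry 18, 13, 21 and 19 passed, 9, 10, 13 and 11 of them with camera in the same direction. Fry does not compare a list with other genes, so a shift of most genes can move it. Under median-ratio scaling and quantile normalization UM101 raised 45.2% and 43.6% of TNF-lowered genes and left 60.9% and 57.5% of the TNF rise. The TNF-called genes were chosen anew under each scaling, and the cause was not tested.

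Changes of sign fell on genes near 0. Under median-ratio scaling and quantile normalization MAPK11 with TNF stood at 0.0494 and 0.0213, MAPKAPK2 at -0.00413 and -0.00352 with SB203580, 0.0551 and 0.0506 with UM101 and 0.0592 and 0.0541 between the compounds, MAPKAPK3 with SB203580 at -0.00383 and -0.0295, and RPS6KA4 with UM101 at 0.0443 and 0.0298. Leaving out each library in turn gave -0.0326 to 0.0183 for MAPK11 and -0.0924 to 0.103 for CSF3 with TNF, -0.00973 to 0.0412 for MAPK11, -0.00644 to 0.0236 for MAPKAPK2 and -0.0226 to 0.0142 for MAPKAPK3 with SB203580, and -0.0508 to 0.115 for HSPB1 between the compounds. It gave 4288 to 4754 genes with TNF, 2375 to 2980 with SB203580, 5490 to 5809 with UM101 and 6104 to 6394 between the compounds.

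The replicate numbers did not pair the libraries: same-number correlations of deviations ran from -0.342 to 0.271, with 5 of 18 over 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate number as a block, 5151, 3010, 6161 and 6678 genes were called, and with SB203580 CCL5 (adjusted p = 0.0599) and ZFP36 (0.0633) were no longer called. The libraries held 104 to 183 M reads. Between replicates of a group, the recovered reads gave a chi-square per degree of freedom of 6.36 to 80.2. The lowest was between DMSO replicates 2 and 3 and the highest between UM101 replicates 2 and 3. Replicates thus differed by more than the sampling of reads gives, on average over genes. Whether depth limited the tests of low genes was not examined.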

Other observations

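Sterol, stress and xenobiotic genes are described here, and the tests of these lists were fixed before the data were examined. Cholesterol synthesis and uptake genes were lower with UM101 than with SB203580 in 19 and higher in 3 of 29 (20 and 3 adjusted over the list alone, camera adjusted p = 0.0283, held in 15 of 19 alternatives; adjusted p = 0.704 with an estimated correlation). HMGCS1 (overlapped by ENSG00000261604) fell with UM101 (-0.68; difference -0.62). Against DMSO the list did not pass with UM101 (camera adjusted p = 0.0748) or with SB203580 (0.236). By fry, a test of the list on its own, it fell with UM101 (adjusted p = 7.89e-05) and rose with SB203580 (0.035).

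Stress lists did not pass camera with UM101, and members moved both ways. By fry, p53 targets (adjusted p = 0.0152) and heat shock genes (0.00543) fell, while ATF4 (0.446) and NRF2 lists (0.055) did not pass. Of 21 heat shock genes 3 rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.987). Their median of -0.0178 turned to 0.0613 under median-ratio scaling and 0.0494 under quantile normalization, so the direction depended on scaling. Among ATF4 and unfolded protein response genes 7 rose and 15 fell of 35 (7 and 16 adjusted over the list alone, camera adjusted p = 0.819), with the phosphatase subunit PPP1R15A at 1.08 and NUPR1 at 1.25, against the cystine transporter SLC7A11 (overlapped by SLC7A11-AS1) at -0.78, or -1.17 with a pseudocount of 0.1. Among p53 targets 4 rose and 9 fell of 20 (4 and 10 adjusted over the list alone, camera adjusted p = 0.858), with GADD45A at 0.85 and MDM2 (overlapped by the gene CPM) at 0.72. Heme oxygenase (HMOX1, 0.44), an NRF2 target, rose, and its list had 3 higher and 4 lower of 21 (2 and 4 adjusted over the list alone, camera adjusted p = 0.923). Of 5 aryl hydrocarbon receptor targets 0 changed with UM101, and CYP1A1 was higher with UM101 than with SB203580 (1.0) and fell with SB203580 against DMSO (-0.94). The list did not pass camera with SB203580 (adjusted p = 0.251) or between the compounds (0.0972). By fry it fell with SB203580 (adjusted p = 0.000777) and was higher with UM101 than with SB203580 (0.000332), and it did not pass with UM101 (0.594).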
